A study of Mus musculus with 9 samples.

How the data were processed

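Genomic DNA of mouse embryonic stem cells of 3 genotypes was bisulfite-sequenced, with 3 replicates of each in the labels. Per the labels' protocols, the cells grew in a serum replacement medium with LIF on irradiated feeder fibroblasts, the DNA was sheared by sonication and TruSeq libraries were read on an Illumina NovaSeq instrument with added PhiX. The submitters' processing notes name FastQC 0.11.7, cutadapt 2.7 and Bismark 0.22.3 and the genome build mm10. The role and settings of each tool, the removal of duplicate reads and any filter are not given in the sources used here. Bisulfite conversion leaves 5-hydroxymethylcytosine unconverted, so a methylated read stands for either base, and WT levels can hold some of it.

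The authors deposited 1 table per genotype with raw read counts per CpG cytosine, pooled over the 3 replicates, and the methylated fraction of those reads. Methylated reads were taken as the deposited fraction times the total count, which was a whole number within 0.05 in every line. Only cytosines with at least 1 read are listed. No column carries a replicate, so no spread between replicates, no replicate left out and no pairing could be had, and 0 columns of per-sample values were left unmatched. The groups come from the labels, and the file of each genotype was matched by the shared start of the sample titles.

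Counts of both strands of a CpG were summed to 1 site. Sites on the autosomes and X with at least 5 reads in each genotype were kept, 92.4% of those with reads. The median depth of the kept sites was 19 reads in WT, 22 in TKO and 20 in SKO, which leaves single sites imprecise, so regions are sums over sites. A level is methylated reads over all reads, with a 95% Wilson interval. A read that covers several CpG sites counts at each of them and molecules read more than once could not be told apart, so the reads of a region are not independent and p-values are too small. Chromosome levels have an SD over the 19 autosomes as a description of evenness, not of replicate error.

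A region needed at least 5 sites. It was called when Fisher's exact test (two-sided) on pooled reads passed a Benjamini-Hochberg adjusted p of 0.05 and the levels differed by at least 20 percentage points. The reference held gene starts and ends on the same build, GRCm38, without strand or sequence. The planned promoters were therefore replaced by the CpG-richer end of each gene: the end with at least 1.5 times as many CpG sites as the other in a window from 1000 bp outside to 500 bp inside the gene, for genes of at least 1500 bp. Of 21627 protein-coding genes on the autosomes and X, 15816 had such an end, and 15464 ends were tested with 8 listed genes of other types. Ends were chosen by CpG number and not by methylation. They had a median of 62 CpG sites and a WT level of 2.44%, against 13 sites and 23.3% at the other end. Windows were consecutive stretches of 10 kb.

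CpG density was the number of sites within 250 bp. Methylation around CTCF motifs and read depth per exon were not analysed here, as no genome sequence or exons were used. Spans of at least 3 consecutive CpG sites under a ratio of 0.25 to WT depth, joined over gaps up to 1000 bp, took the place of exons. Relative depth left out very deep sites, those with over 68 reads in WT, 77 in TKO or 74 in SKO.

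The 12 gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the targeted genes, the 10 ends with the largest TKO gain and up to 10 with the largest loss with at least 10 sites and 100 reads in each genotype, up to 4 members of each list, the 5 ends highest in SKO and the 5 windows with the largest gain or loss. Predicted genes were passed over, 1 among the gains and 1 among the ends highest in SKO, and no loss met the rule. A list's median difference was ranked among 10000 random lists matched on deciles of WT level, as a description of these libraries. The lists were pluripotency, fibroblast, germ cell, 2-cell stage, imprinted, developmental regulator, trophoblast, NuRD, CTCF and cohesin, DNA methylation machinery, clustered protocadherin and housekeeping genes.

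The calls were tested on simulated reads at the real depths. These reads were independent draws without spread between replicates, as Fisher's exact test assumes. The false calls therefore do not measure the effect of replicate spread or of reads that cover several sites. At the gene ends of TKO against WT, 49 of 50 changes of 25 points and 50 of 50 of 30 points were recovered, with 1 false call among 15256 unchanged ends. For SKO against WT 48 of 50 changes of 25 points were recovered with 0 false calls. Unchanged ends there had the SKO level, a median of 1.46% in the real data, in both simulated libraries. These 0 false calls therefore do not measure the error at ends of higher level. In the windows of TKO against WT, 50 of 50 changes of 25 points were recovered with 0 false calls among 252381. Alternatives covered the read minimum, the size of difference, the number of sites, the weighting of sites, very deep sites, the shift of the median, the windows, the choice of ends and the chromosomes. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and matplotlib 3.10.9.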

Results

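Bisulfite sequencing measured CpG methylation in mouse embryonic stem cells of 3 genotypes: unmodified cells (WT), cells without the 5-methylcytosine dioxygenases Tet1, Tet2 and Tet3 (TKO), and cells without both those 3 genes and the DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b (SKO). The labels list 9 samples, 3 replicates of each genotype, and the authors pooled the replicates of a genotype into 1 set of values, so no spread between replicates could be measured. The tests below therefore compare the pooled libraries of 2 genotypes and not the conditions, and every interval covers counting error only. Reads at CpG cytosines numbered 387231455 in WT, 436927379 in TKO and 406215343 in SKO, over 40129991, 40309292 and 40219388 cytosines. With both strands of a CpG summed, the median site on the autosomes and X had 19, 21 and 20 reads. The comparisons used 19090251 sites with at least 5 reads in each genotype.

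The targeted genes were read first, as a check of the labels. In SKO, reads were nearly missing from most of Dnmt3b, a de novo DNA methyltransferase gene: over chromosome 2, 153661191 to 153686622 (mm10), a span of 293 CpG sites inside the gene, the depth was 2.09% of that in WT (95% interval 1.76 to 2.46), with each genotype scaled to its own median autosomal site. Dnmt3a, the other de novo methyltransferase gene tested, had a span of 526 sites at chromosome 12, 3872860 to 3910054, with 2.30% of the WT depth (2.01 to 2.61). Tet3 had a short span at chromosome 6, 83404272 to 83404466, with 9.76% of the WT depth in TKO (5.32 to 16.7). In SKO the span at 83404272 to 83404426 had 10.9% (5.65 to 19.5). A span of 107 bp and 4 CpG sites in Tet1, at chromosome 10, 62840211 to 62840317, had 16.8% of the WT depth in SKO (8.80 to 29.9) and 26.3% in TKO (15.8 to 42.4), just above the limit used to find spans. A short span of 3 sites in Dnmt3a, at chromosome 12, 3819217 to 3819323, had 19.7% in SKO (9.29 to 38.2). In TKO, where Dnmt3a is not targeted, it had 37.6% (21.8 to 62.8). Another Dnmt3a span of 42 sites, at 3912043 to 3914087, had 19.5% in SKO (16.7 to 22.7) and 93.1% in TKO (85.3 to 102). A dense Dnmt3a span of 205 sites, at 3806706 to 3807961, had 51.6% in SKO (46.4 to 57.3) and 122% in TKO (113 to 133). Its depth exceeds the limit because runs of low sites were joined over gaps. Short spans were picked for low depth and untargeted genes were not scanned, so those in Tet1 and Tet3 are a weak check. No span of at least 3 sites under a ratio of 0.25 was found in Dnmt1 or Tet2 in either knockout. A deletion that holds no CpG site would not be seen.

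The loss of the Tet enzymes, which oxidise 5-methylcytosine on the way to its removal, went with a gain of methylation across the genome. The methylation level of CpG sites on the autosomes and X was 24.6% in WT and 54.7% in TKO, a difference of 30.1 percentage points and a ratio of 2.22. It was 3.03% in SKO, 21.6 points below WT (difference SKO minus WT -21.6). The TKO difference had an SD of 1.21 points between the 19 autosomes and ranged over them from 27.2 to 32.1 points. The 95% Wilson intervals were 24.59 to 24.60% in WT, 54.70 to 54.71% in TKO and 3.031 to 3.034% in SKO, since they rest on 379776217, 427159042 and 398222009 reads.

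Single sites moved with the average. Among 16796024 sites with at least 10 reads in each genotype, the median site was at 20% in WT, 60.9% in TKO and 0% in SKO. Sites at 80% or more made up 1.04% of all in WT, 17.8% in TKO and 1.19e-04% in SKO. The TKO level was above the WT level at 89.1% of the sites and at least 20 points above it at 67.2%, and it was at least 20 points below it at 0.436%. Among all sites with at least 5 reads, those at 5% or less in WT had a TKO level of 26.9%, sites of 20 to 50% had 65.6% and sites of 80% or more had 81.9%. Sites sorted by their own WT reads drift toward the average in another library, so part of the difference in the lowest and highest classes comes from the sorting.

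**Figure D1:**
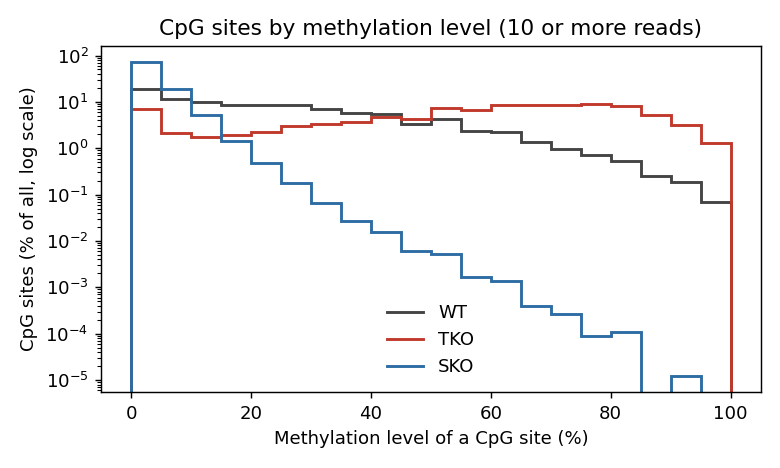
Share of CpG sites (percent of all sites, log scale) by methylation level (percent, in steps of 5) in WT, TKO and SKO, over sites with at least 10 reads in each genotype; each line is the pooled libraries of 1 genotype. The median site lay at 20% in WT, 60.9% in TKO and 0% in SKO.

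The TKO gain reached the CpG-rich ends of genes unevenly. The largest gains were at Rtl4, a retrotransposon-derived gag-like gene, and Trpc5, a cation channel gene, whose windows overlap on the X chromosome. Rtl4 (144687209 to 144688708) went from 1.46% in WT to 80.9% in TKO, and Trpc5 (144687681 to 144689180) from 0.855% to 79.2%. B3galt5, which encodes a galactosyltransferase (chromosome 16, 96234801 to 96236300), rose from 6.79% to 81.2%. Map4, which encodes a microtubule-associated protein (chromosome 9, 110083455 to 110084954), rose from 10.4% to 82.5%.

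A pair of X-linked germ cell genes followed: Nxf2, of an mRNA export factor family, rose from 6.70% to 78.8% (134964255 to 134965754), and Tex13b, a testis-expressed gene, from 10.1% to 79.96% (140812934 to 140814433). Slc24a5, a cation exchanger of pigment cells (chromosome 2, 125067127 to 125068626), rose from 9.79% to 78.0%, and Dcun1d4 (chromosome 5, 73480010 to 73481509) from 6.04% to 71.8%. Sytl3, of the synaptotagmin-like family (chromosome 17, 6737571 to 6739070), rose from 16.8% to 81.8%, and Fbxo40, a muscle F-box gene (chromosome 16, 36990031 to 36991530), from 3.21% to 67.9%. Among these 10, SKO levels ran from 1.65% at Dcun1d4 to 13% at Trpc5. The adjusted p of Fisher's exact test (two-sided, Benjamini-Hochberg) was 3.3e-40 at Trpc5, the least deeply read of them with 117 reads in WT, and 1.7e-199 at Dcun1d4.

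Of 15464 gene ends tested, 3622 (23.4%) were higher in TKO by at least 20 points and past an adjusted p of 0.05, and 1 was lower. The 1 lower end, at the predicted gene Gm52446 on X, fell from 83.7% of 49 reads to 63.5% of 52 reads (adjusted p = 0.0338, Fisher's exact test); it has 8 sites, lies outside the rule for named genes and was named after its value was seen. The median end was at 2.44% in WT and 7.81% in TKO, with a median difference of 5.24 points. The count moved with the choice of ends, from 1069 with a stricter choice to 6093 with an end taken for every gene, both tried after the data were seen. An end with more CpG sites need not be the transcription start.

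Germ cell genes gained most among the gene lists fixed before the data were examined: 20 of 28 tested rose and none fell. Their median end went from 6.68% in WT to 41.8% in TKO, and their median difference of 34 points lay at the 99.98th percentile of 10000 random lists matched on WT level. Asz1 and Piwil2, of the piRNA pathway, rose from 15.0% to 69.2% and from 15.0% to 65.9%. The homeobox gene Rhox13 rose from 18.3% to 77.6%, and Dpep3, a testis dipeptidase, from 14.9% to 68.5%. Of the trophoblast list, 5 of 10 rose, at the 98.43rd percentile. The X-linked homeobox genes Rhox6 and Rhox9 rose from 7.26% to 61.0% and from 4.15% to 53.2%, Plac1 from 18.8% to 63.0% and Prl3d1, which encodes a placental lactogen, from 13.2% to 49.6%. The Prl3d1 end had 9 kept sites. With at least 10 reads per site, 1 trophoblast gene rose.

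Developmental regulators had low levels in WT (median 1.43%) and TKO (6.4%), yet their median difference of 5.44 points was at the 99.69th percentile, and 7 of 40 rose. Tbx5, a heart and limb regulator, rose from 5.91% to 61.5%, Nkx2-1, of lung and thyroid, from 9.71% to 50.6%, Hoxc4 from 9.87% to 50.3% and Hoxb1 from 6.26% to 36.4%. The Hoxc4 end had 8 kept sites. Of the clustered protocadherins, cell adhesion genes, 1 of 15 rose, Pcdhb22, from 27.8% to 59.5%. The list's median difference was 9.95 points, at the 98.85th percentile, and Pcdhb1, Pcdhgb8 and Pcdhac1 differed by 17.7, 15.5 and 15.5 points. Of the fibroblast markers, listed because the cells grew on feeder fibroblasts, 7 of 16 rose, at the 97.99th percentile: Col1a1 went from 3.45% to 53.4%, Lum from 20.1% to 68.8%, Postn from 17.7% to 65.2% and Col6a1 from 23.9% to 63.6%.

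The pluripotency genes stayed low: 2 of 15 rose, and the median end was at 1.02% in WT and 2.64% in TKO. The 2 were Dppa3, which protects methylation in the early embryo, from 11.8% to 63.1%, and the nuclear receptor gene Nr5a2, from 20.5% to 67.9%. Prdm14 and Fgf4 differed by 5.09 and 3.33 points. Of 15 housekeeping genes none rose, with Hprt, B2m, Rplp0 and Psmd1 at differences of 7.03, 5.84, 4.96 and 4.46 points. These lists lay at the 26.57th and 11.54th percentiles. Of genes for the NuRD complex, a nucleosome remodelling and deacetylase complex named in the series title, 1 of 15 rose: Chd5, from 2.69% to 25.5%. Chd4, Mbd2 and Hdac2 differed by 17.2, 5.35 and 3.87 points, and the list lay at the 23.07th percentile. The NuRD count was 2 with at least 10 reads per site and 0 with a shorter window.

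Of the genes for CTCF and cohesin, which fold chromosomes into loops, 4 of 12 rose, at the 22.49th percentile: Ctcfl, a testis relative of Ctcf, from 11.4% to 61.1%, Stag1 from 4.56% to 48.9%, Rad21 from 33.7% to 72.7% and Wapl from 41.3% to 70.4%. Of the DNA methylation machinery, 3 of 14 rose, at the 76.19th percentile: Zbtb38, which encodes a methyl-CpG binding protein, from 11.3% to 69.2%, Dnmt1 from 25.1% to 72.7% and Dnmt3a from 26.7% to 58.4%. The end of Tet3 differed by 14.7 points. The ends of Rad21, Wapl, Dnmt3a and Dnmt1 had 14, 9, 13 and 31 kept sites and WT levels of 25.1% or more. All CpG-richer ends had a median of 62 CpG sites and 2.44% in WT, the poorer ends 13 and 23.3%. Whether these ends hold the promoter is not known, as strand was not used. The dense Dnmt3a span of 205 sites, at 3806706 to 3807961, lies outside the tested end of that gene. It was at 1.597% in WT and 1.549% in TKO, so the rise at the tested Dnmt3a end does not extend to it. The 2-cell-stage list had 4 of 5 higher: Zscan4d rose from 33.1% to 61.0%, Zscan4c from 36.2% to 63.7%, Zscan4a from 35.2% to 60.4% and Usp17lc from 28.4% to 54.5%. The ends of Zscan4d, Zscan4c and Zscan4a had 9, 7 and 8 kept sites. The Zscan4 genes are close copies of each other, so reads may be shared among them, and the list lay at the 39.62nd percentile.

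Imprinted genes gained less than other ends of their WT level. Random lists were matched on WT level and not on CpG density, with which the gain also differed. An end already high in WT has little room to gain. Their median end was at 16.2% in WT and 33.3% in TKO, the median difference of 8.12 points compared with 22.4 in matched random lists (0.02nd percentile), and 6 of 31 rose. H19, a non-coding RNA gene, rose from 26.5% to 75.4%, Mest from 12.1% to 47.2%, Snrpn from 6.25% to 33.3% and Peg10 from 17.0% to 43.3%. The Snrpn end had 8 kept sites and 80 reads in WT. The counts adjusted over the list alone were equal to those over all ends for all 12 lists. At a threshold of 10 points the protocadherin count was 7, the imprinted count 12 and the developmental regulator count 11.

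**Figure D2:**
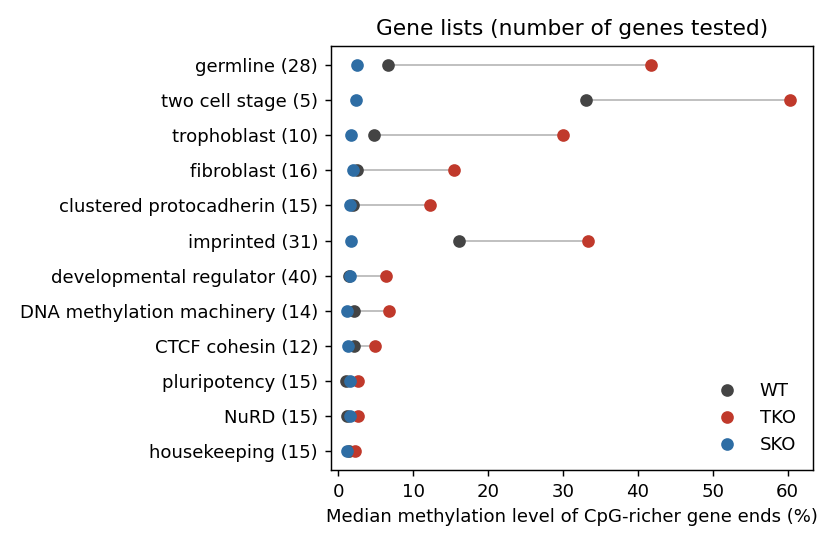
Median methylation level (percent) of the CpG-richer gene ends of each fixed gene list in WT, TKO and SKO, with the number of genes tested in brackets; grey lines join WT and TKO. Germ cell genes went from a median of 6.68% to 41.8%, and the median of the housekeeping genes was under 3% in all genotypes.

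Windows of 10 kb gave the change without gene annotation. The largest gain was at chromosome 17, 6740001 to 6750000, inside Ezr, which encodes a linker of membrane and actin, from 15.9% in WT to 83.5% in TKO. Next came a window in Spred2, a Ras pathway inhibitor (chromosome 11, 20020001 to 20030000), from 11% to 75%, and a window without a protein-coding gene (chromosome 4, 78510001 to 78520000), from 12% to 75.6%. Windows at Fat1, an atypical cadherin (chromosome 8, 44950001 to 44960000), and Zfp532 (chromosome 18, 65620001 to 65630000) rose from 13.9% to 76.0% and from 12.2% to 74.3%. Of 252581 windows, 191183 (75.7%) were higher in TKO and none was lower by at least 20 points. The median window differed by 28.3 points. With that shift taken off, 2319 windows were higher and 3375 lower, a balance that the centring itself brings about.

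The gain depended on how dense the CpG sites were. Sites with 6 to 19 CpG within 250 bp went from 24.9% in WT to 61.3% in TKO, those with 5 or fewer from 26.7% to 53.5%, and those with 20 or more, the density of CpG islands, from 6.34% to 14.2%. The differences were 36.4, 26.8 and 7.90 points. At 60 or more CpG the level was 1.38% in WT, 1.37% in TKO and 1.27% in SKO. The highest TKO level in finer classes, 62.9%, was at 8 to 10 CpG, where WT had 25.1%. The same counts were also used in a density window of 500 bp on each side. The differences were then 33.8, 22 and 23.9 points for the middle, sparse and dense class, with the dense class above the sparse one. The counts were not scaled to the wider window, so each class holds less dense sites than before. The orders of unlike classes do not test each other.

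**Figure D3:**
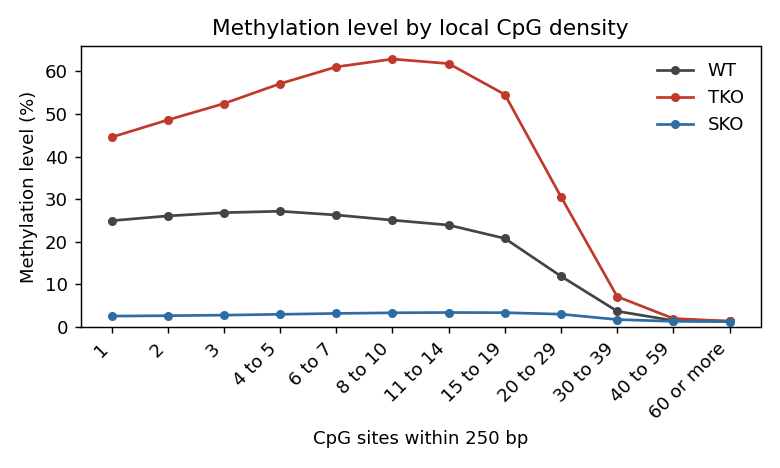
Methylation level (percent) of CpG sites by the number of CpG sites within 250 bp, in WT, TKO and SKO. TKO peaks at 62.9% at 8 to 10 CpG and falls to 1.37% at 60 or more, where WT is at 1.38%.

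In SKO, without the methyltransferases, methylation was low at almost every gene end. The imprinted genes Igf2 and H19 fell from 71.8% in WT to 11.4% and from 26.5% to 2.54%. Rdh9, of the retinol dehydrogenase family, fell from 62.4% to 12% and Fbxw23 from 53.9% to 11.8%. Of 15464 gene ends, 1346 (8.70%) were lower in SKO than in WT and none was higher by at least 20 points (two-sided Fisher's exact test). Most ends could not fall by 20 points from a median WT level of 2.44%. Of the 252581 windows of 10 kb, 150431 (59.6%) were lower in SKO, and of 19225 gene bodies 7405 (38.5%), with none higher in either. Of the lists, 12 of 31 imprinted genes, 4 of 5 of the 2-cell stage, 2 of 12 of CTCF and cohesin and 2 of 14 of the methylation machinery were lower, with 1 each among fibroblast and protocadherin genes and none in the other 6 lists.

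The highest level left in SKO was 29.9% at Vmn2r29, a pheromone receptor gene with close copies (WT 45%, TKO 62.6%; chromosome 7, 7277790 to 7279289). The end at Trpc5 was at 13% in SKO and 0.855% in WT (adjusted p = 7.4e-04, Fisher's exact test), a difference below 20 points. The count of lower ends moved to 463 at a threshold of 30 points and 2591 at 10 points. It was 332 with a stricter choice of ends and 2462 with an end for every gene, both tried after the data were seen.

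The methylation left in SKO was not even across sites. Mitochondrial DNA was read at 1.39% in SKO (95% Wilson interval 1.36 to 1.42), 1.43% in TKO and 1.69% in WT. Nuclear sites at 5% or less in WT had an SKO level of 2.01% and sites at 80% or more in WT had 6.16% (6.14 to 6.19). Sorted by TKO level, the SKO level was 1.28% at sites of 5% or less and 4.40% at sites of 80% or more. Dense, middle and sparse CpG sites were at 2.15%, 3.30% and 2.85%. Of 10399593 sites with at least 20 SKO reads, 593 were at 50% or more, and their level was 69.9% in WT and 81.8% in TKO.

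**Figure D4:**
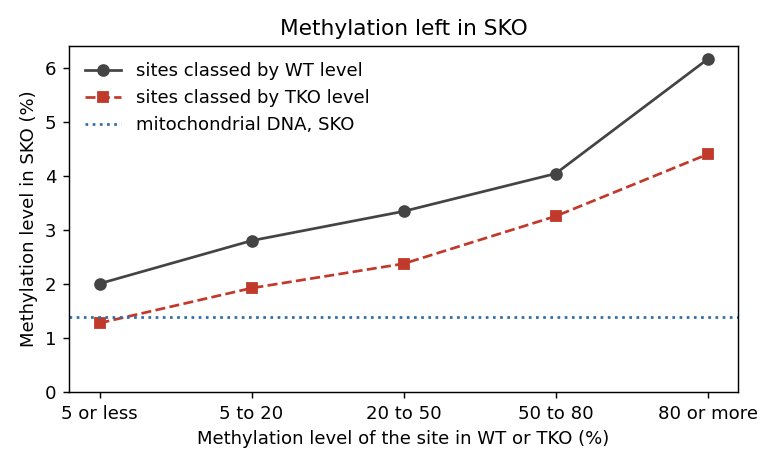
Methylation level in SKO (percent) of nuclear CpG sites sorted by their level in WT or in TKO, with the SKO level of mitochondrial DNA, 1.39%, as a dotted line. The SKO level runs from 2.01% to 6.16% over the WT classes and from 1.28% to 4.40% over the TKO classes.

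By chromosome, the X stood below the autosomes in TKO. X had 25.9% in WT, 50.6% in TKO and 2.84% in SKO, a TKO difference of 24.7 points against 27.2 to 32.1 over the autosomes. Chromosome 9 had the smallest autosomal difference, 27.2 points, with the highest WT level, 29.4%. It had 20.3 WT reads per site and chromosome 17 had 18.7, at relative depths, without very deep sites, of 1.01 and 1. Over all chromosomes very deep sites were at 51.4% in WT and 53.1% in TKO. The levels by chromosome include them. Whether they lower the difference of chromosome 9, the low end of the autosomal range, was not tested. The X had a depth of 0.457, 0.463 and 0.473 relative to the median autosome in WT, TKO and SKO. Depth also differed on autosomes: chromosome 1 up to a step between 120 and 130 Mb was at 1.47, 1.49 and 1.49 of the median autosome, the first 100 Mb of chromosome 8 at 1.36 in WT, 1.05 in TKO and 0.966 in SKO, and chromosome 12 at 0.955, 0.967 and 0.728. On chromosome 1 the last 2 steps of 5 Mb before the drop were deeper still, at 2.23 to 2.41. The distal end of chromosome 8, past a step after 100 Mb, was at 1.49, 1.55 and 1.51, and chromosome 14 at 1.15, 0.950 and 0.948. On chromosome 15 the step of 5 Mb from 60 Mb was at 0.965, 1.35 and 1.49. Genotypes differed by over 1.2 times in steps of 5 Mb on chromosomes 8, 12, 14 and 15, in 19 of 26, 24 of 24, 14 of 25 and 2 of 21 steps, and in none on the other autosomes.

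**Figure D5:**
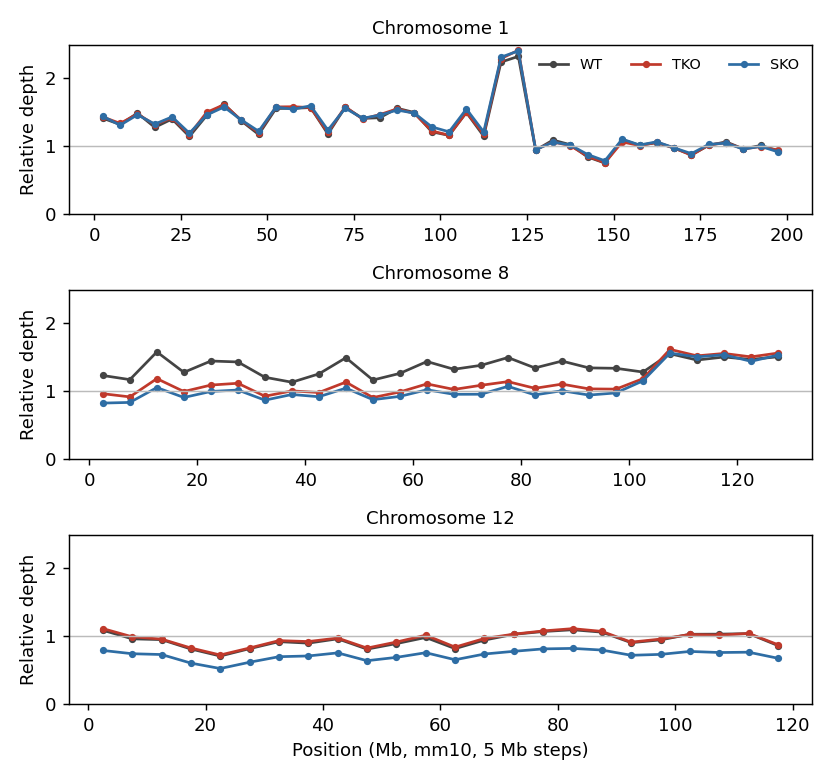
Depth at CpG sites relative to the median autosome of the same genotype, in steps of 5 Mb along chromosomes 1, 8 and 12 (mm10, Mb), in WT, TKO and SKO; the grey line marks 1. Chromosome 1 up to the step between 120 and 130 Mb averages 1.47 to 1.49 in the 3 genotypes and reaches 2.23 to 2.41 just before it, and chromosome 12 is at 0.728 in SKO.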

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

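The tests of chromosome 8 and chromosome 12 were chosen after their depth was seen, and the test of chromosome 1 was set before its result.

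The Y chromosome, outside the comparisons, was at 39.3% in WT, 50.6% in TKO and 4.88% in SKO, above the 1.39% of mitochondrial DNA. The 43 unplaced and random contigs, also outside them, were at 57.4% in WT, 59.9% in TKO and 3.53% in SKO.

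Chromosome 12 had a relative depth of 0.728 in SKO and chromosome 8 one of 1.39 in WT, read from depth, a quantity outside the methylation comparisons, and chromosome 1 had a step in all 3 genotypes. Among sites of like CpG density chromosome 1 up to its step between 120 and 130 Mb was 1.49 times as deep as the rest in WT, which argues against density as the cause of that step. The ratio of WT to SKO depth follows from depths already seen. It was 1.41 over the first 100 Mb of chromosome 8 and 1.31 over chromosome 12. Composition or mappability of a sequence that the lines share cannot differ between them. The effect of composition on depth can differ between libraries, which was not tested. The labels name no parent strain, so a sequence difference between the lines also stays open for chromosomes 8 and 12. Mappability stays open for the step on chromosome 1. Gains or losses of these chromosomes in all or part of the cells of a line are a candidate explanation that was not tested on its own.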

How the results depend on the processing

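The choices of an end for every gene, of ends with 3 times as many CpG sites and of leaving out chromosomes 1, 8 and 12 were made after the data were seen; all other alternatives were planned. No paired analysis was possible because the pooled columns carry no replicate numbers. The fits with edgeR and limma, the replicates left out in turn, the replicate block and the 3 alternatives for CTCF motifs were not run for want of replicates or sequence. Of 151 alternative values, 85 stayed the same, that is within 1.5 times of a main count or within the counting error of a main level or depth. No single difference changed sign, but counts, levels and depths have no sign to change. Only the TKO differences by density class and chromosome could, and their main values were gains of 7.90 to 36.4 points. The balance of higher and lower windows turned round by the centring itself. The order of the sparse and the dense class did so with counts not scaled to a wider window, so between unlike classes. Without chromosomes 1, 8 and 12 the counts of gene ends in TKO and SKO and of windows in TKO moved by less than 1.5 times. Only these counts were run so. A count falls by the calls on the chromosomes left out, so this limit cannot decide whether the depth steps affect the calls. Other chromosomes whose depth differed between genotypes were kept in. The cause of a moved value was not tested unless said. Depth limits single sites most, and the pooled reads leave no measure of replicate error.

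The WT level was 24.6% with at least 1 read per site, 24.8% with 10, 26.3% with 20, 24.6% on autosomes alone, 23.7% as a mean of single sites and 24.1% without very deep sites. TKO had 54.5%, 55.7%, 58.0%, 54.8%, 53.8% and 54.7% in that order, and SKO 3.04%, 3.05%, 3.14%, 3.04%, 2.99% and 3.02%. These exceed counting intervals that are very narrow. In SKO, sites at 5% or less in WT were at 2.02%, 2.03% and 2.02% with at least 1 read, with 10 and without very deep sites, and sites at 80% or more in WT at 6.22% with 10 reads and 6.13% without very deep sites. With at least 10 reads the TKO difference was 27.6 points on chromosome 9, 26 on X, and 27.1, 36.6 and 9.36 points at low, middle and high density. With a density window of 500 bp on each side it was 22, 33.8 and 23.9, with the dense class above the sparse one. The counts that set the classes were not scaled to that window. The Dnmt3a span had 2.93% of the WT depth when scaled to the 100 kb on both sides.

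Gene ends higher in TKO numbered 5462 at 10 points, 6093 with every gene and 1069 with 3 times as many sites, where fewer ends were tested. The 1 lower end became 0 with at least 10 reads, with 10 CpG sites, with 500 bp outside, at 30 points and with 3 times as many sites. Ends lower in SKO numbered 2591 at 10 points, 463 at 30 points, 2462 with every gene and 332 with 3 times as many sites, and 1 end was higher at 10 points. Windows higher in TKO numbered 112593 at 30 points, 2319 with the median shift taken off, 844383 at 2 kb and 20864 at 100 kb, where the number of windows itself changes. Windows lower in TKO numbered 2 with at least 1 read, 1 with 10 reads, 3 at 10 points, 29 at 2 kb and 3375 with the shift taken off. At 10 points 5 genes of the methylation machinery, 2 of NuRD, 7 protocadherins, 11 developmental regulators, 12 imprinted and 8 trophoblast genes were higher. With at least 10 reads 2 NuRD genes and 1 trophoblast gene were higher, and with 500 bp outside 0 NuRD genes.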

Other observations

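The values on gene bodies, families and deep sites were read after the main results, and the tests of DNA from other cells and of thinned reads were chosen after the result was seen.

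Gene body levels were summarised by family. Over 19217 protein-coding gene bodies the median level was 21% in WT and 52.6% in TKO, a median difference of 30.8 points. Odorant receptor genes (Olfr, 159 bodies) had 21.8% in WT and 40.6% in TKO, with a median difference of 18.2 points. The pheromone receptor families Vmn1r and Vmn2r differed by 12.7 and 12.8 points, from 23.7% and 22.8% in WT. Solute carriers (Slc, 374 bodies) differed by 32.8 points and collagens (Col, 44) by 32.4. Hox bodies were at 2.71% in WT and 11.8% in TKO, ribosomal protein genes (Rpl and Rps) at 2.05% and 9.54%, and protocadherins (Pcdh) at 9.20% and 33.2%. Receptor families hold close copies that can share reads, and families were not compared by a test. Among 10000 random sets of gene bodies of the same size, not matched on WT level, the median difference lay at or under the 0.36th percentile for 12 of 15 families, so low values were not particular to the receptors. These 12 were Olfr, Vmn1r, Vmn2r, Zfp, Pcdh, Hox, Rpl and Rps, Defb, Skint, Ugt, Cyp and Serpin. The other 3 were Slc at the 99.97th, Col at the 84.98th and Psm at the 74.51st.

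Some bodies were already methylated in WT: Trim5 had 72.5% in WT and 76.1% in TKO, the epidermal gene Flg2 69.4% and 75.5%, and Vnn3 64.0% and 77.4%. The imprinted gene Nnat had 54.0% in WT and rose to 79.1%. Bodies picked for a high WT level drift toward a smaller difference by that choice. The 28360 deepest sites, above 68 reads in WT, 77 in TKO or 74 in SKO, were at 51.4% in WT and 53.1% in TKO, while all other sites were at 24.1% and 54.7%.

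Methylated reads were left in SKO at 3.03% of nuclear CpG reads. Incomplete conversion alike at every CpG would give 1 level, but sites at 80% or more in WT exceeded sites at 5% or less by 4.15 points. Conversion that differs with CpG density alone is argued against by a gap of 3.18 points within the middle density class, between sites at 80% or more and at 5% or less in TKO. DNA of feeder or other cells would also bring reads to the deleted span of Dnmt3b, where methylated SKO reads were 0.446% of the reads of an intact span (95% Poisson interval 0.305 to 0.629), below the excess of 1.64 points over mitochondrial DNA, so it could account for part of that excess. Conversion that differs with sequence features other than density, and methylation kept from before the knockout or made by another activity, stay open and were not tested.

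The X chromosome gained 24.7 points in TKO and the autosomes 30.2, with an SD of 1.21 between autosomes. CpG density and WT level are each argued against as the whole cause, since autosomal sites weighted to those of X gained 28.4 and 28.5 points. Both values lie below 30.2, so each could account for part, and the weightings were not combined. Classes of WT level rest on single sites, which are shallower on X. Autosomal sites weighted to the depth of X gained 19.7 points, over 1 SD below X, but shallow autosomal sites need not be like X sites, which are shallow along the whole chromosome, so the planned criterion was not a test of depth. Autosomal sites thinned at random to the depth of X gained 31.2 points, but thinning leaves the expected level of a site unchanged, so this decides nothing either and depth stays open. A biological difference of X also stays open and was not tested, as the design names no group for it.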
